A study of Mus musculus with 4 samples.

How the data were processed

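Poly(A)-selected RNA was sequenced from mouse embryonic stem cells in which both Cbx2 alleles are floxed and carry a HaloTag. Per the labels, 2 libraries came from cells given ethanol (EtOH) as a day 0 control and 2 from cells given 1.0 µM 4-hydroxytamoxifen (4-OHT) for 48 hours, called day 2 knockout here. All 4 libraries are labelled as batch 2. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries were made with NEBNext poly(A) selection and Ultra II RNA kits, per the labels' protocols, which do not say whether strand was kept.

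The deposited values are TPM (a length-corrected share of transcripts), a unit that divides estimated reads by transcript length and scales each library to a total of 1000000. The authors' steps included Trim Galore and Salmon with the mouse build GRCm38 (mm10), per the submitters' processing notes, which give no version or order. The annotation release and Salmon's bias settings are not given in the sources used here. The table holds 22266 genes. It also holds 2 columns of values that match no sample used here, and these were not used. Because TPM keeps no depth, the depth of each library is unknown and no counting interval or detection floor was computed. Of the genes listed, 4509 stood at 0 in all 4 libraries.

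Values were analysed as log2(TPM + 1), so a fold change is on the log2(TPM + 1) scale and understates the change of genes of low expression. Genes with a mean of at least 1 TPM over the 4 libraries were kept, which left 12029. The groups were compared with limma (version 3.58.1, in R 4.3.3; linear model and moderated statistics with a mean-variance trend, two-sided, residual degrees of freedom 2, prior degrees of freedom 4.01). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors are limma's moderated ones. An exact permutation test of 2 against 2 cannot give a two-sided p below 0.333, so no single-gene permutation test was run. On 20 simulated data sets of 12029 genes with 200 changed, the fit recovered 37.6% of 2-fold and 93.7% of 4-fold changes. It made 138.55 calls on average, of which 7 were false. The changes were set on the log2(TPM + 1) scale, and a further 25 genes were shifted by 0.5 as a list. The simulated noise was independent between genes and equally large in both groups, unlike in these libraries, so the rates may not carry over.

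Before the data were examined, 24 gene lists were fixed: PRC1 subunits, PRC2 subunits, Hox genes, developmental regulators silenced by Polycomb, naive pluripotency, formative epiblast, mesendoderm, primitive endoderm, neuroectoderm, trophoblast, 2-cell-like, germline, p53 targets, cholesterol synthesis, ATF4 and the integrated stress response, interferon response, cell cycle, imprinted, X-linked, fibroblast and feeder cell markers, mitochondrially encoded mRNAs, immediate early, replication-dependent histones and estrogen receptor targets. Some genes stand on more than a single list. Each list with at least 5 members tested was compared with the other genes by limma's camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 24 lists. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation, camera's test rests on the 2 residual degrees of freedom, so it could hardly pass after adjustment over 24 lists. Errors of list medians are bootstrap standard errors over members (2000 draws), and percentiles come from 10000 random lists of the same size matched on mean expression in 20 bins. Members were also adjusted over the list alone.

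The genes named were set by a rule fixed before the data were examined: Cbx2, up to 12 genes per direction with the largest change among those past the threshold whose libraries do not overlap between groups, leaving out predicted gene models, then up to 6 per direction with the smallest p that did not pass where fewer than 12 did, and up to 4 members of each list with the smallest p. Predicted gene models past the threshold are named too and were chosen after their values were seen. The values of 1 gene that the rule selects are not reported here. Coordinates, transcript lengths and GC content come from GENCODE mouse release 21 (GRCm38), to which 22213 of the gene identifiers matched without their version numbers. Only 11 matched with version, so the authors' annotation was another release. Near-identical copies were sought with blastn 2.17.0, requiring 95% identity over at least 50% of a transcript. Plots were drawn with matplotlib in Python.

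Alternatives fixed before the data were examined were pseudocounts of 0.1, 0.5 and 5, no filter on low values, a minimum of 5 TPM, median of ratios scaling, quantile normalization, limma without a trend, robust moderation, a test against a fold change of 1.5, a replicate block, and leaving out each library in turn. Added after the data were seen were leaving out mitochondrially encoded genes, weights estimated per group, removal of each library's trend with transcript length and GC content by splines, and leaving out genes with a near-identical copy.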

Results

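Expression was measured by poly(A) RNA sequencing in 4 libraries from mouse embryonic stem cells kept in serum with leukemia inhibitory factor. The cells are female (line PGK12.1) and carry floxed, HaloTag-bearing Cbx2. CBX2 is a chromodomain subunit of canonical Polycomb repressive complex 1 (PRC1), a complex that compacts chromatin and helps keep developmental genes silent. The EtOH group (n = 2, day 0) still carries Cbx2, and the OHT group (n = 2, day 2) received 1.0 µM 4-OHT for 48 hours to delete it. The labels do not name the deleted exons or the recombinase, and no library here combines 4-OHT with intact Cbx2, so the drug, the time in culture and the deletion cannot be separated. The values are the authors' TPM, which keeps no depth, so the depth behind each value is unknown. The comparison asks which transcripts differ soon after loss of CBX2.

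Cbx2 (ENSMUSG00000025577.8, GRCm38 chromosome 11, 119022962 to 119031270, plus strand, protein-coding) was read at 2.29 and 2.71 TPM in the EtOH libraries and at 0.749 and 1.14 TPM in the OHT libraries. The SD was 0.300 TPM with EtOH and 0.275 TPM with OHT (n = 2 each), and the ratio of the group means was 0.377. Both OHT libraries lay below both EtOH libraries, in the direction the labels give. The log2 fold change of -0.85 (SE 0.19) had a limma adjusted p of 0.265 over 12029 genes, so Cbx2 did not pass the threshold. With 1 library left out, it passed without OHT replicate 1 (adjusted p = 0.0292) or 2 (0.0128), a fit in which the lone OHT library is assumed to vary like the EtOH pair; without EtOH replicate 1 or 2 the adjusted p was 0.741 and 1. The fold change depends on the pseudocount at these low levels, with -1.34 at a pseudocount of 0.1 and -0.34 at 5. TPM covers the whole transcript, so exons outside the deleted part can still give signal.

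Few transcripts separated the groups past the threshold. Cyp2e1, which encodes a xenobiotic-oxidising cytochrome P450 (chromosome 7, 140763739 to 140774987, plus strand), fell from 10.1 ± 1.00 TPM with EtOH to 0.394 ± 0.197 TPM with OHT (SD, n = 2 each), a log2 fold change of -3.00 (SE 0.19, limma adjusted p = 0.0265). Among the 5 genes past the threshold it was the only one for which the search found no near-identical copy. The other 4 are predicted gene models, named after their values were seen. Gm6763 fell from 18.7 and 15.2 TPM to a listed 0 in both OHT libraries (adjusted p = 0.00635), Gm3839 fell by 2.33 and Gm8797 by 1.95 on the log2 scale, and Gm4340 rose by 1.45 (adjusted p = 0.0265 for each of these 3). In all, 1 gene was higher and 4 were lower.

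Each of these 4 gene models shares sequence with transcripts whose reads can be split between them. Gm6763 and Gm4340 lie close together on chromosome 10 (104151497 to 104153965 and 104194042 to 104196522) in a family of predicted genes with up to 100% identity. Its most abundant member, Gm21293, read 234 and 232 TPM with EtOH and 130 and 126 TPM with OHT. Summed over the family around Gm6763, TPM was 305 and 296 with EtOH and 238 and 240 with OHT. Gm3839 is 99.2% identical to Gapdh, which read 7157 and 7147 TPM with EtOH and 7850 and 8411 TPM with OHT. Gm8797 is 98.2% identical to the ubiquitin gene Ubb, at 1763 and 1777 TPM with EtOH and 2030 and 2013 TPM with OHT. The values of these 4 models are therefore uncertain.

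**Figure D1:**
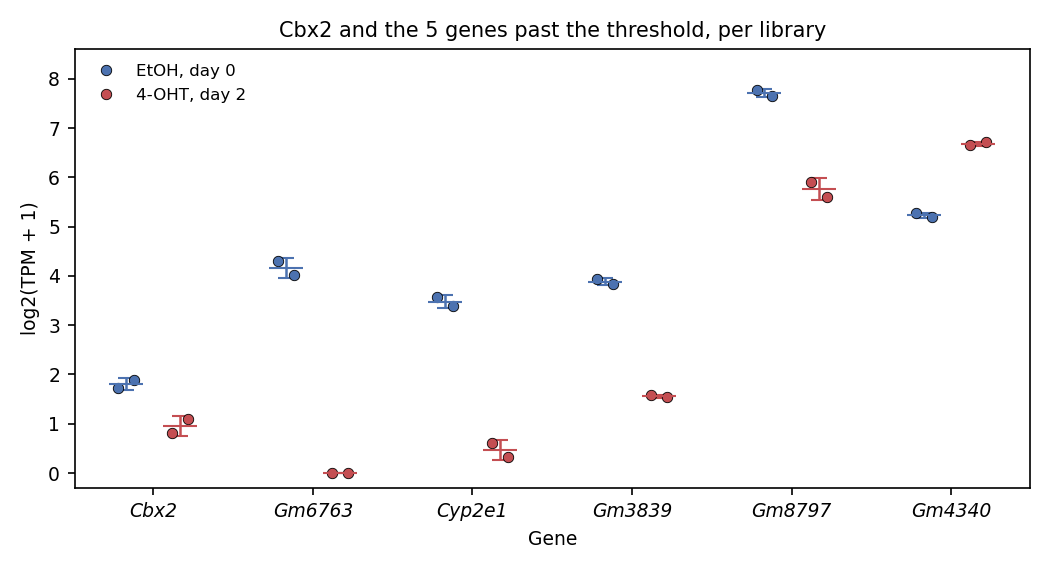
Cbx2 and the 5 genes past the threshold. The vertical axis is log2(TPM + 1); points are single libraries (blue, EtOH day 0; red, 4-OHT day 2; 2 per group), wide dashes are group means and bars are 1 SD. Cbx2 is lower in both OHT libraries without passing the threshold, Gm6763 is listed at 0 in both, and Gm4340 is the only gene past the threshold that is higher with OHT.

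Beyond these, 1260 genes had an unadjusted p under 0.05 (724 higher, 536 lower; 601.45 would be expected by chance), and 29 had an adjusted p under 0.1 (16 higher, 13 lower). The smallest p-values that did not pass, among higher genes, belonged to Nupr1 (a stress-induced chromatin protein), Tpi1 (the glycolytic triosephosphate isomerase) and Lefty2 (a Nodal antagonist), each with adjusted p = 0.0615. Nupr1 read 21.2 ± 1.55 TPM with EtOH and 57.7 ± 1.83 TPM with OHT, Tpi1 read 239 ± 5.27 and 440.2 ± 1.89 TPM, and Lefty2 read 110.2 ± 1.38 and 224 ± 14.9 TPM (SD, n = 2 each). They were followed by the histone genes H2bc4 (log2 fold change 1.16, SE 0.12) and H2ac7 (1.84, SE 0.20) and by Chac1 (1.38, SE 0.16), which encodes a glutathione-degrading enzyme. On the lower side stood Popdc3 (-1.84, SE 0.17) and the small GTPase gene Rab33b (-1.27, SE 0.16), neither with a near-identical copy. Eif1ad17 (-1.62), H2ac13 (-1.92), Pagr1a (-2.28) and the ferritin light chain gene Ftl1 (-1.01) also stood there, and like H2ac7 each has near-identical copies. Summed over the gene and its copies, TPM moved on the log2 scale by -0.46 for Eif1ad17, 0.14 for H2ac13 and -0.04 for Pagr1a. The sums moved by 0.15 for Ftl1 and 0.14 for H2ac7, so the values of these single genes are uncertain.

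The libraries of the 2 groups did not overlap for 5105 genes, 42.4% of those tested, where chance gives 33.3%. The EtOH libraries lay closer together (SD over genes of their log2 difference 0.18) than the OHT libraries (0.35), and the median log2 fold change of all tested genes was 0.02. When the genes were split evenly into low, middle and high mean expression, the unadjusted p was under 0.05 for 369 higher and 159 lower genes of low, 196 and 104 of middle, and 159 and 273 of high expression. Of the genes past the threshold, 3 lower ones were of low expression, none of middle, and 1 higher and 1 lower of high expression. Across 11973 genes, which are not independent replicates, the difference between the OHT libraries followed log2 transcript length (Pearson r = 0.56, Spearman rho = 0.62), and that between the EtOH libraries did so too (r = 0.29, rho = 0.38). Removing each library's trend with length and GC content, an alternative chosen after seeing the data, gave 74 genes past the threshold (42 higher, 32 lower), with the 5 among them. The count was 46 and 34 without EtOH replicate 1 or 2 and 2957 and 2478 without OHT replicate 1 or 2, where the spread then comes from the remaining pair alone. The direction turned with the OHT library that was kept: 2222 were higher and 735 lower without OHT replicate 1, and 728 higher and 1750 lower without OHT replicate 2, with the median of all tested genes at 0.14 and -0.09. Median of ratios scaling and quantile normalization each gave 0 higher and 3 lower, and without a filter on low values none passed, with 1838 genes at an unadjusted p under 0.05.

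Neither of the Polycomb complexes passed as a group. Of 24 PRC1 subunits tested, none passed over all genes or adjusted over the list alone, and their median log2 fold change was 0.06 (SE 0.08, camera adjusted p = 0.822). That median was -0.14 in OHT replicate 1 and 0.23 in OHT replicate 2, each against the EtOH mean, and 0.01 without EtOH replicate 1. At an unadjusted p under 0.05 stood 2 subunits, Cbx2 and Pcgf6 (82.8 ± 0.759 TPM with EtOH, 62.9 ± 4.44 with OHT). Cbx8, another chromodomain subunit, read 1.81 and 1.40 TPM with EtOH and 2.73 and 2.28 TPM with OHT, a log2 fold change of 0.43 (SE 0.18, adjusted p = 0.495). Of the 12 subunits of PRC2, the complex that methylates H3K27, none passed either (median -0.09, SE 0.05, camera adjusted p = 0.102; -0.18 in OHT replicate 1 and 0.03 in OHT replicate 2). The accessory subunit gene Phf19 (-0.66, SE 0.22) and Rbbp7 (-0.24, SE 0.09) were the 2 with an unadjusted p under 0.05.

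Hox genes, classical Polycomb targets, were shifted upward as a list. Of 39 fixed, 15 were expressed enough to test, and their median log2 fold change was 0.28 (SE 0.09, camera adjusted p = 0.00877; adjusted p = 0.770 with an estimated correlation). None passed singly, over all genes or adjusted over the list alone, and 5 had an unadjusted p under 0.05, all higher. Both OHT libraries lay above both EtOH libraries for 9 and below for 1. Levels were low: Hoxd8 read 1.17 ± 0.130 TPM with EtOH and 2.29 ± 0.103 with OHT, Hoxc4 0.670 ± 0.115 and 1.45 ± 0.149, Hoxc13 5.44 ± 0.391 and 7.97 ± 0.326, and Hoxa7 1.43 ± 0.0922 and 2.55 ± 0.645 (SD, n = 2 each). The list's median stood at the 97.1st percentile of random lists of like expression. Its call was lost under quantile normalization (median 0.19, adjusted p = 0.0506) and without OHT replicate 1 (median 0.37, adjusted p = 0.291).

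Of 90 developmental regulators listed in advance as silenced by Polycomb in mouse embryonic stem cells, 37 reached a mean of 1 TPM and were tested. Silencing itself was not measured here. The list's median log2 fold change of 0.12 stood at the 76.0th percentile of random lists of like expression, not extreme among them. Adjusted over the list alone 3 rose and 1 fell, and none passed over all genes. Among those that rose were Sox1 (2.86 ± 0.337 to 6.02 ± 1.05 TPM) and Tlx1 (0.725 ± 0.0445 to 1.75 ± 0.0346 TPM), transcription factors of neural and spleen development, while Pax6, an eye and neural regulator, fell (7.45 ± 0.161 to 3.39 ± 0.303 TPM; SD, n = 2 each). As a list they did not pass (median 0.12, SE 0.03, camera adjusted p = 0.151), except without OHT replicate 2, where the adjusted p was 0.0232 (median 0.11). Without OHT replicate 1 the median was 0.25 while camera's direction turned to down (adjusted p = 0.952).

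Genes of the ATF4 and integrated stress response list, the program that follows amino acid shortage or protein folding stress, were higher as a list. Of 24 members tested, both OHT libraries lay above both EtOH libraries for 21, with a median log2 fold change of 0.52 (SE 0.09), and the list passed camera (adjusted p = 8.38e-15; adjusted p = 0.770 with an estimated correlation). None passed over all genes, while 17 rose and 1 fell when adjusted over the list alone. Besides Nupr1 and Chac1, the pseudokinase gene Trib3 rose from 10.9 ± 1.15 to 25.9 ± 2.61 TPM and the mTOR inhibitor gene Ddit4 from 51.6 ± 1.31 to 92.8 ± 2.28 TPM (SD, n = 2 each). Atf4 itself, named after its value was seen, was among those that rose (log2 fold change 0.49, SE 0.09). The 1 that fell was Hspa5, the chief chaperone of the endoplasmic reticulum (-0.23, SE 0.09), likewise named afterwards.

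p53 targets and DNA damage genes were also higher as a list (29 tested, median 0.19, SE 0.06, camera adjusted p = 1.81e-04; adjusted p = 0.770 with an estimated correlation). Adjusted over the list alone 4 rose and none fell, and none passed over all genes. They were the stress cytokine gene Gdf15 (log2 fold change 1.29, SE 0.16), the apoptosis gene Pmaip1 (0.97, SE 0.13), the cell cycle inhibitor gene Cdkn1a (0.70, SE 0.11) and Perp (0.46, SE 0.10). The median was 0.08 in OHT replicate 1 and 0.32 in OHT replicate 2, each against the EtOH mean, and without OHT replicate 2 the adjusted p was 0.00741. Immediate early genes passed as well (21 tested, median 0.15, SE 0.08, camera adjusted p = 0.0178, and 0.770 with an estimated correlation). Atf3 and Jund were the 2 that rose when adjusted over the list alone, and Atf3 stands on the ATF4 list too. The list's call came at a median on the 96.9th percentile of random lists of like expression. That call was lost without EtOH replicate 2 (median 0.13, adjusted p = 0.143), and, at a larger median, without OHT replicate 1 (0.27, adjusted p = 0.267) and with the length and GC trend removed (0.19, adjusted p = 0.0739). It held without OHT replicate 2, at a median of 0.09.

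Histone genes were higher as a list (16 tested, median 0.48, SE 0.13, camera adjusted p = 4.05e-07; adjusted p = 0.770 with an estimated correlation). Adjusted over the list alone 6 rose and none fell, and none passed over all genes. H2bc4 rose from 26.9 ± 0.0758 to 61.2 ± 3.83 TPM, H3c15 from 2.33 ± 0.432 to 7.48 ± 0.0498, H1f0 from 24.4 ± 0.587 to 40.2 ± 4.48, and H1f2 from 12.2 ± 0.943 to 21.6 ± 2.95 (SD, n = 2 each). H1f0 is a linker histone whose mRNA is made outside S phase, so it does not do what the list's name says. H3c15 has a near-identical copy in H3c14, and TPM summed over both moved by 1.21 on the log2 scale. With genes that have a near-identical copy left out, the list kept its call (7 tested, median 0.69, camera adjusted p = 5.50e-07). Most replication-dependent histone mRNAs lack a poly(A) tail, and these libraries were poly(A) selected. The list's call was lost without OHT replicate 1 (median 0.38, adjusted p = 0.267).

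Mitochondrially encoded mRNAs were lower as a list (13 tested, median -0.55, SE 0.04, camera adjusted p = 5.94e-11; adjusted p = 0.770 with an estimated correlation). Both OHT libraries lay below both EtOH libraries for 12 of the 13. Adjusted over the list alone 9 fell and none rose, and none passed over all genes. mt-Co2 fell from 7400 ± 148 to 5048 ± 103 TPM, mt-Nd1 from 3759 ± 105 to 2697 ± 329, mt-Atp6 from 6562 ± 91.0 to 4789 ± 206 and mt-Nd6 from 99.8 ± 14.4 to 49.3 ± 7.91 (SD, n = 2 each). Their summed share of all TPM was 4.26% and 4.35% with EtOH and 2.93% and 3.38% with OHT. With the length and GC trend removed the median was -0.24 (adjusted p = 0.0253), and without OHT replicate 1 it was -0.36.

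**Figure D2:**
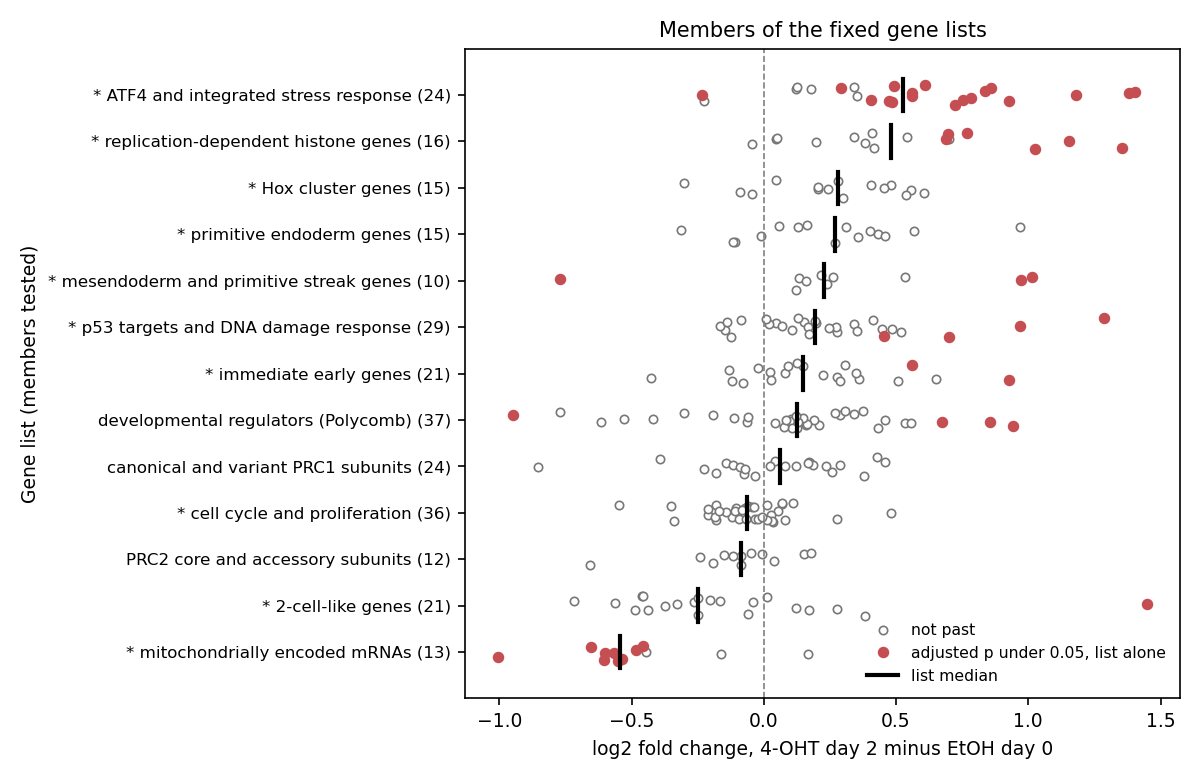
Members of 13 gene lists by log2 fold change on the log2(TPM + 1) scale (horizontal axis, 4-OHT day 2 minus EtOH day 0). Points are genes (filled, adjusted p under 0.05 over the list alone), black lines are list medians, stars mark lists past camera with the preset correlation, and the number of members tested is in parentheses. The ATF4 list has its median at 0.52 and the mitochondrially encoded mRNAs at -0.55.

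Pluripotency genes did not pass as a list, and those that passed within it went both ways. Of 30 naive and general pluripotency genes, Klf2 (444 ± 17.3 to 595 ± 38.8 TPM) and Tbx3 (57.9 ± 0.781 to 93.3 ± 18.1 TPM) rose, and Dppa3 (108 ± 5.30 to 65.3 ± 9.71 TPM) and Lin28a (183 ± 4.16 to 132 ± 14.3 TPM; SD, n = 2 each) fell when adjusted over the list alone (camera adjusted p = 0.684). Of 17 formative and primed epiblast genes none passed adjusted over the list alone (median -0.06, adjusted p = 0.187; -0.23 in OHT replicate 1, 0.11 in OHT replicate 2, and -0.11 and 0.03 without EtOH replicate 1 or 2), with Lef1 (-0.68, SE 0.15) and the DNA methyltransferase gene Dnmt3b (-0.51, SE 0.17) the smallest in p; the list passed as lower with the length and GC trend removed (adjusted p = 0.0305).

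Mesendoderm genes passed as higher (10 of 22 tested, median 0.23, SE 0.12, camera adjusted p = 0.00877, and 0.770 with an estimated correlation). Their median stood at the 96.6th percentile of random lists of like expression, below that of the Hox list. Lefty2 and Lefty1 (66.4 ± 5.38 to 131 ± 9.09 TPM, SD, n = 2 each), Nodal antagonists that embryonic stem cells also express, rose when adjusted over the list alone, and the streak regulator Evx1 fell (-0.77, SE 0.20). The call was lost without a filter on low values (median 0.05, adjusted p = 0.588) and without OHT replicate 1 (0.32, adjusted p = 0.270), and the median was 0.14 without OHT replicate 2. Primitive endoderm genes passed too (15 of 23 tested, median 0.27, SE 0.11, adjusted p = 0.0110; adjusted p = 0.770 with an estimated correlation), none singly, with Apoe at 0.43 (SE 0.10) and Hnf4a at 0.97 (SE 0.27). Their median was 0.04 in OHT replicate 1 and 0.40 in OHT replicate 2, and the call was lost without OHT replicate 2 (adjusted p = 0.0853), without a filter on low values (median 0.12, adjusted p = 0.232) and with the length and GC trend removed (median 0.14, adjusted p = 0.129).

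Of 12 neuroectoderm genes, Sox1 and Crabp1 rose and Pax6 and Crabp2 fell when adjusted over the list alone (camera adjusted p = 0.873). Of 14 trophoblast genes, the X-linked homeobox genes Rhox9 (-0.77, SE 0.15) and Rhox6 (-0.65, SE 0.14) fell when adjusted over the list alone while the median was 0.23 (adjusted p = 0.370), and 0.09 without OHT replicate 2. In the 2-cell-like list (21 tested) the median was -0.25 (SE 0.09, camera adjusted p = 0.0404; adjusted p = 0.770 with an estimated correlation). Its only member past the threshold, Gm4340, went the other way. Summed over Gm4340 and its near-identical copies, TPM moved by -0.32 on the log2 scale. Tdpoz4 (-0.72, SE 0.18) and Eif1ad7 (-0.46, SE 0.15) were the next by p. The call held in 7 of the 16 other settings that altered its test, with estimated correlation and fry not counted. It was lost without each of the 4 libraries in turn, with medians of -0.23 and -0.14 without EtOH replicate 1 or 2, -0.05 without OHT replicate 1 and -0.38 without OHT replicate 2 (adjusted p from 0.0622 to 0.234). It was also lost with genes that have a near-identical copy left out (0.03, adjusted p = 0.729), with the length and GC trend removed (-0.14, adjusted p = 0.363), with mitochondrially encoded genes left out (-0.26, adjusted p = 0.0520) and with a minimum of 5 TPM (-0.26, adjusted p = 0.159). Germline genes (19 tested) had a median of -0.08 (adjusted p = 0.406), which was -0.14 without EtOH replicate 1 and -0.13 without EtOH replicate 2, and camera's direction turned to up without OHT replicate 2 (adjusted p = 0.744). Their member Dmrtb1 rose when adjusted over the list alone (0.96, SE 0.18).

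Cell cycle genes lay slightly lower as a list (36 tested, median -0.06, SE 0.03, camera adjusted p = 0.0234, and 0.770 with an estimated correlation). None passed adjusted over the list alone. The list's median stood at the 18.2nd percentile of random lists of like expression, so it was not extreme among them. Ccne2, the cyclin of S phase entry, had the smallest p (22.3 ± 0.956 TPM with EtOH and 14.9 ± 0.717 with OHT, SD, n = 2 each), followed by Mycn (-0.34, SE 0.11). The call was lost under quantile normalization (median -0.01, adjusted p = 0.328), without EtOH replicate 2 (-0.03, adjusted p = 0.202) and without OHT replicate 1 (0.05, adjusted p = 0.334). It was lost at a median no smaller in size with a minimum of 5 TPM (-0.07, adjusted p = 0.0518) and without EtOH replicate 1 (-0.09, adjusted p = 0.133), and held without OHT replicate 2, at -0.17.

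The remaining lists did not pass. Grb10, a growth factor receptor adaptor, rose when adjusted over the 25 imprinted genes tested (13.3 ± 0.399 to 29.3 ± 5.62 TPM, SD, n = 2 each; camera adjusted p = 0.471 for the list), and Stc2, a secreted glycoprotein gene also induced by stress, rose when adjusted over the 7 estrogen receptor targets (1.40 ± 0.0628 to 5.54 ± 0.477 TPM; adjusted p = 0.268). No member passed adjusted over the list alone among 26 cholesterol genes (median 0.10, adjusted p = 0.151; -0.07 in OHT replicate 1, and 0.26 in OHT replicate 2, with adjusted p = 0.0450 without OHT replicate 1), 10 interferon response genes (median 0.09, adjusted p = 0.520) or 11 fibroblast and feeder cell markers (median 0.22, adjusted p = 0.260). The interferon median was 0.03 without EtOH replicate 2, 0.05 without OHT replicate 2 and 0.04 without OHT replicate 1, where camera's direction turned to down (adjusted p = 0.920), and the fibroblast median was 0.10 without OHT replicate 2. The 40 X-linked genes listed had a median of 0.01 and a mean of -0.01, and camera's direction was down (adjusted p = 0.752); the median was -0.20 in OHT replicate 1, 0.12 in OHT replicate 2, and -0.05 and 0.06 without EtOH replicate 1 or 2. All 504 tested genes of the X chromosome had a median log2 fold change of 0.01, against 0.02 for 11499 autosomal genes, at the 26.9th percentile of matched random lists.

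Across the 24 lists, camera with the preset correlation called 10 (7 higher, 3 lower). With an estimated correlation it called none (smallest adjusted p = 0.770, with 1 list at an unadjusted p under 0.05). Fry called none for a common direction (smallest adjusted p = 0.169, with 3 lists at an unadjusted p under 0.05). Both of these tests rest on 2 residual degrees of freedom, so the absence of calls does not show that no list moved. Fry's mixed test, which asks whether members change in either direction, passed 17 lists.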

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

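Leaving out mitochondrially encoded genes, weights per group, removal of the length and GC trend and leaving out near-identical copies were chosen after seeing the data. The 5 genes past the threshold (1 higher, 4 lower) numbered 7 with a pseudocount of 0.1 (2 higher), 0 without a filter on low values (0 higher, 0 lower; more genes tested), 3 (0 higher, 3 lower) with median of ratios scaling, quantile normalization and limma without a trend, 1 (0 higher, 1 lower) against a fold change of 1.5 and with near-identical copies left out, 36 (19 higher, 17 lower) with weights per group and 74 (42 higher, 32 lower) with the length and GC trend removed; where not stated, the cause was not tested. Leaving out a library gave 34 to 2957 genes (12 to 2222 higher, 22 to 1750 lower), mostly higher without OHT replicate 1 (2222 against 735 lower) and mostly lower without OHT replicate 2 (1750 against 728 higher), the lone library being assumed to vary like the other group. With a replicate block the count was 474 (261 higher, 213 lower) and Cbx2 stayed at -0.85 with limma adjusted p = 0.00308. The prior degrees of freedom were infinite there, so each gene took the trend's variance and its own spread was not used. The labels do not pair the libraries. Their replicate differences correlated across genes (r = 0.29), but those of both groups followed transcript length, so this need not mean pairing. The block ended the calls of the 2-cell-like (median -0.25, camera adjusted p = 0.193) and cell cycle lists (-0.06, camera adjusted p = 0.121) with their medians as they were. Cbx2 ranged from -0.998 to -0.708 without a library. The lists called numbered 6 with a minimum of 5 TPM, where the 2-cell-like and cell cycle calls were lost and the Hox and mesendoderm lists had too few members to be tested, 5 to 9 without a library, and 0 with an estimated correlation or fry. Estimated correlation and fry aside, the ATF4, p53 and mitochondrial lists kept their call in every other setting that tested them (16, 16 and 15). Limma without a trend and robust eBayes, which left camera's test as it was, were not counted. Of 1934 values of 104 other named genes, 1652 kept their side of the threshold, 267 newly passed, 15 no longer passed and none reversed. TPM keeps no depth, so counting error was not assessed.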

Other observations

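The tests of the glycolysis, hypoxia and oxidative phosphorylation lists and the Fisher test on near-identical copies were chosen after the results had been seen; the other tests here were chosen before theirs. Glycolytic genes lay higher in the OHT libraries. Of 19 tested, both OHT libraries lay above both EtOH libraries for 16 and below for none, with a median log2 fold change of 0.29 (0.19 in OHT replicate 1 and 0.34 in OHT replicate 2, each against the EtOH mean), although none passed over all genes. Tpi1, Aldoa (1035 ± 0.0823 TPM with EtOH, 1563 ± 73.3 with OHT) and Ldha (929 ± 7.32 and 1275 ± 9.69 TPM, SD, n = 2 each) had the smallest p, named after their values were seen. The hypothesis that the pathway as a group is higher was tested on the 16 members not yet looked at when the list was written. Their median was 0.31 (0.19 in OHT replicate 1 and 0.40 in OHT replicate 2). With the preset correlation camera gave p = 6.48e-08 (adjusted p = 1.94e-07 over the 3 lists written after the data were seen). With an estimated correlation camera gave p = 0.199 (adjusted p = 0.386). That second test rests on 2 residual degrees of freedom and could hardly pass, so the hypothesis stays open.

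Targets of the hypoxia-inducible factor (HIF) showed the same direction, with a median of 0.27 over 22 tested genes (0.18 in OHT replicate 1 and 0.37 in OHT replicate 2) and 0.24 over the 19 not looked at before (camera adjusted p = 1.33e-04; adjusted p = 0.386 with an estimated correlation). Nuclear-encoded genes of oxidative phosphorylation had a median of 0.02 over the 34 not looked at before (camera adjusted p = 0.935), with 0.07 in OHT replicate 1 and -0.08 in OHT replicate 2. The mitochondrially encoded ones lay at -0.55, and whether both sets differ was not tested. Of the HIF targets, and named after their values were seen, Vegfa read 6.84 ± 0.181 TPM with EtOH and 20.1 ± 2.95 with OHT, and Bnip3 25.6 ± 1.77 and 50.3 ± 3.28 TPM (SD, n = 2 each; adjusted p = 0.0995 and 0.110 over all genes). Ddit4 and Stc2 stand on the HIF list as well as on lists described above, and Pgk1, Slc2a1 and Ldha stand on both the HIF and the glycolysis list.

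The ATF4 list was higher in both OHT libraries (medians 0.50 and 0.56 against the EtOH mean). The list lay 0.50 above the median of all tested genes before normalization and 0.54 above it (SE 0.08) under quantile normalization. A scale factor shifts the list and all genes nearly alike, so it could hardly change this difference, nor could it produce it. Under median of ratios scaling the list's median was 0.49, with that of all tested genes at -0.01. These values argue against a scale factor as the source of the ATF4 list's rise. Transcript length and GC content leave a median of 0.49 (SE 0.09) after both are regressed out, against 0.52 before. Whether the rise follows loss of Cbx2 or 4-OHT, ethanol or culture time and medium use stays open. The reason is that 0 libraries received 4-OHT with Cbx2 intact, so these explanations cannot be told apart here. A stress response to the treatment may thus account for the pattern as well as a response to loss of CBX2.

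The Hox list, a Polycomb target group, was higher by 0.28. It lay 0.26 above the median of all genes before normalization and 0.19 above it (SE 0.08, over members) under quantile normalization, where its call was lost. A scale factor could hardly change this difference. With levels on this list so low and its call lost, the comparison is not read as deciding about scaling. A shift shared by all genes of low expression was not excluded: the list's median lay at the 97.1st percentile of matched random lists, inside the bound that had been set. Most lists of like expression still lay lower, so the test does not show that such a shift accounts for the rise. With 0 libraries given 4-OHT with intact Cbx2, an effect of the drug or of time in culture cannot be told apart from derepression after loss of CBX2.

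The predicted gene models past the threshold may reflect how reads were divided between near-identical copies. The summed TPM of the family of Gm6763 and Gm4340 moved by -0.33 on the log2 scale (pooled SD 0.02), less than the 1.45 of Gm4340, the smaller of the 2 changes. Of 29 genes with an adjusted p under 0.1, 12 have such a copy, but the copies of most had been looked up before that count was made. Without the 22 already searched or found as copies, 2 of 7 have one, against 721 of 11831 other genes (6.09%, Fisher's exact test, two-sided p = 0.0637). This leaves open whether such copies matter beyond the genes already searched. Among those searched, the sums over copies of H2ac7 (0.14), H2ac13 (0.14), Pagr1a (-0.04), Ftl1 (0.15) and Eif1ad17 (-0.46) also moved by less than the gene itself. A different haplotype at such a locus or a true change of a single copy was not tested.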
